A study of Bos taurus with 14 samples.

How the data were processed

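Transcript levels were measured on 14 single-colour microarrays of bovine embryos collected at the 16-cell stage, 96 hours after insemination. Per the labels, zygotes produced in vitro were grown 25 to a well of 500 µl in synthetic oviduct fluid (SOF) medium under 4 conditions, and each array received RNA from a pool of 20 embryos. Labelling followed the kit's protocol for 25 ng of RNA, per the labels, and used the Cy3 dye alone. Arrays were placed in groups by their titles in the labels, which give 4 arrays at 5% O2 without feeder cells (replicates 1 to 4), 3 at 20% O2 without feeder cells (replicates 2 to 4), 3 with BOEC at 20% O2 (replicates 1 to 3) and 4 with VERO cells at 20% O2 (replicates 1 to 4).

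The scanner files deposited for each array hold spot values as fluorescence intensity. Per the file headers and the submitters' processing notes, they were extracted with Agilent Feature Extraction 10.7.3.1 from a custom bovine design whose probe positions refer to genome build UMD 3.1. The processed intensity used here had been detrended over the slide surface and background-subtracted by Feature Extraction, per the file headers, and its low values had been replaced by surrogate values. The mean, median and local background intensities of each spot in the deposited files are raw pixel values. Flags, 0 or 1 for each spot, are given per the file headers for signal well above background, for saturation and for uneven spots. The authors also deposited 1 table of log2 values for all arrays. Each of its columns had a median of 0 and equalled the log2 median intensity of a spot minus the array's median, with a largest absolute difference of 4.974e-14 and 100% of values within 0.001, so its scale, centring and direction were settled from the values. That table holds no background subtraction and was used as an alternative. How the authors tested for differences is not given in the sources used here.

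Of 62844 spots on an array, 61325 were not controls, and these belonged to 52960 probes. The 8365 probes with 2 spots were averaged, and the correlation between such spots lay between 0.981 and 0.993 across probes on the 14 arrays. Spots marked as outliers, 0 to 13 on an array, were left out, and no spot was saturated. Values were log2 processed intensity minus the array's 75th percentile over probes that are not controls, averaged over the spots of a probe. A probe was tested when it was well above background on at least 3 of the 14 arrays, whichever their groups, which kept 31249 probes. Probe names come from the design: 25477 probes were named through a transcript accession in the gene table supplied for this species, 10781 through a symbol and 1155 through an older symbol, while 6373 kept the name in the file, 884 carried a retrovirus name and 8290 had none. The tested probes covered 12623 named genes, 12500 of them with a usable symbol. For gene lists and named genes a gene was represented by its tested probe with the highest mean over the 14 arrays, and probes of the same gene that disagreed are given where the gene is described.

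Differences were tested with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8, handled the tables), using lmFit and eBayes with default settings on all 14 arrays and 4 group means, so that the groups share 1 estimate of the spread (10 residual degrees of freedom per probe, 2.18 prior degrees of freedom). Tests were 2-sided. P-values were adjusted by Benjamini-Hochberg over all tested probes within a comparison, with a threshold of 0.05, and every adjusted p for a gene below is limma's. The 7 comparisons were 20% against 5% O2, BOEC against 20% O2, VERO against 20% O2, the mean of both co-cultures against 20% O2, BOEC against VERO, and each co-culture against 5% O2. A moderated F test over all groups was added. Errors given with log2 differences are standard errors from the fit, and those given with group levels are standard deviations.

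The 29 gene lists covered the response to low oxygen, antioxidant genes, p53 targets, apoptosis, the unfolded protein response, heat shock, embryonic genome activation, maternal oocyte transcripts, inner cell mass, trophectoderm, primitive endoderm, cell junctions, glycolysis, oxidative phosphorylation, lipid metabolism, cholesterol synthesis, interferon-stimulated genes, chromatin, imprinted genes, growth factors, cell cycle, ribosomal proteins, mRNA processing and prostaglandin and steroid synthesis. They also covered markers of oviduct epithelium, stroma, cultured adherent cells, cumulus cells and leukocytes. Each list with at least 5 tested genes was tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over all lists and the 7 comparisons together. Camera with a correlation estimated from the data, and fry, were the other set tests. Fry's test asks whether a list's genes move on balance 1 way, and it does not compare the list with other genes.

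The comparisons, the lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names, in each comparison, the 10 largest rises and 10 largest falls (all where fewer) among genes past the threshold whose 2 groups of arrays did not overlap. It also names up to 4 members past the threshold from each list, and for a list that was called without 2 such members, or that is described as unchanged, the 2 to 4 members with the largest moderated t. Not every gene that the rule selects is named in the text, and some are not reported here.

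The share of probes well above background ranged from 51.9% to 62.1% between arrays, the 75th percentile of processed intensity from 215 to 530, and the median local background from 24 to 34. For arrays, the number of arrays rather than a count limits the precision. The test was first run on simulated data with known changes in 31249 probes. It recovered 4.48% to 16.4% of probes changed by 0.5 on the log2 scale over the 7 comparisons, 38.8% to 53.7% of those changed by 1 and 81.8% to 89.4% of those changed by 2.

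The 14 arrays lay on 2 slides of 7 arrays each, and all 4 groups were on both slides. Slide 1 held the arrays numbered 1 and 2, and slide 2 those numbered 3 and 4. Groups share replicate numbers in the labels, which do not say what a number stands for. Whether arrays with the same number deviate together from their group means was checked by correlation across probes: every 1 of 3 pairs exceeded the preset minimum of 0.1 for BOEC and VERO (0.11 to 0.231), and in no other combination with at least 3 pairs did every pair do so. The fit with the replicate number as a block is therefore given beside the comparison of BOEC with VERO.

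The alternatives were other scalings (median of each array, quantile normalization, normexp background correction with offset 50 followed by quantile normalization, and the authors' table), other filters on dim probes (none, or above background on all 14 arrays), limma's trend and robust options, array weights, slide or replicate number as a block, an added threshold of 1 on the log2 scale, only the arrays compared, each array left out in turn, and for lists the mean of all probes of a gene. Each slide on its own, 2 arrays that stand apart left out, a stromal score as covariate and the named genes with only the arrays compared were added after seeing the data. Sequences and coordinates beyond those in the files were not used.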

Results

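Gene expression was compared between bovine 16-cell embryos grown at 5% O2, the control condition per the labels (n = 4 arrays), at 20% O2 (n = 3), and at 20% O2 on feeder cells, either BOEC (n = 3) or VERO (n = 4). BOEC is the field's usual short name for bovine oviduct epithelial cells, the lining of the tube in which the early embryo develops, and VERO is a kidney cell line of the African green monkey. Nothing in the labels says whether the pools of 20 embryos in a group came from separate cultures. P-values thus measure the spread between these arrays, part of which may be technical. Correlation between arrays of a group lay between 0.971 and 0.986 at 5% O2, 0.981 and 0.985 at 20% O2, 0.966 and 0.981 with BOEC, and 0.973 and 0.982 with VERO cells. No pair of arrays was identical, and the leading principal components held 22.3% and 14.1% of the variance. By limma's moderated F test, 2096 of 31249 probes differed in some group. That count was 910, 1079 and 845 without the arrays numbered 2, 3 and 4 at 20% O2, 1123 and 1314 without those numbered 1 and 2 with VERO cells, and 1319 without that numbered 2 with BOEC.

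Values are log2 intensities relative to the 75th percentile of their array, and differences are log2 differences with their standard error. For a gene that was not well above background on any array of a group, its level there is only bounded. The difference is then also given as at least N-fold, the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the gene's own signal and the lowest signal that was well above background on that array. Unless stated otherwise, every array of 1 group lay beyond every array of the other for the genes named as having risen or fallen. Rise and fall mean past the threshold of 0.05 on limma's adjusted p.

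The comparison of 20% with 5% O2 without feeder cells asked what atmospheric oxygen alone changed. PAG11, which encodes a pregnancy-associated glycoprotein of the ruminant trophoblast (chromosome 29, 40130397 to 40148837 in UMD 3.1), rose by 1.96 (SE 0.258, adjusted p = 0.0369), and its other probe rose by 6.63. The orphan receptor gene GPR137C rose by 1.49 (SE 0.209, adjusted p = 0.0369), and RPRM, a p53-inducible inhibitor of the cell cycle, rose by 0.86 (SE 0.115, adjusted p = 0.0369). The anion exchanger gene SLC4A3 fell by 1.02 (SE 0.152, adjusted p = 0.0469), and CACNB1, a subunit of voltage-gated calcium channels, fell by 0.95 (SE 0.15, adjusted p = 0.0481). After normexp background correction the rises of GPR137C and RPRM were 0.58 and 0.54 and the fall of SLC4A3 was −0.67.

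Among gene lists, p53 targets shifted upward, with a median difference of 0.255 over 17 tested genes of which 14 were positive (camera adjusted p = 0.0245, but adjusted p = 0.812 with an estimated correlation). The shift kept its sign under every scaling, at a smaller 0.142 with the median as scale. None of the 17 passed alone by limma over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. CCNG1, a cyclin induced by p53, differed by 0.49 (SE 0.151, adjusted p = 0.168) and SESN1, a stress-induced sestrin, by 0.48 (adjusted p = 0.306). Ribosomal protein genes shifted downward, with a median of −0.238 over 77 genes of which 4 were positive (adjusted p = 8.4e-17, but adjusted p = 0.812 with an estimated correlation), a sign kept under every scaling, at −0.0458 with quantile normalization. Of these 77 genes 0 passed alone by either adjustment and 37 had an unadjusted p under 0.05. Across arrays the 75th percentile of intensity was 307 to 467 at 5% O2, and 395 to 530 at 20% O2. RPL22L1 differed by −0.52 (SE 0.116, adjusted p = 0.0865) and RPS15 by −0.44 (adjusted p = 0.155). Genes of mRNA processing shifted downward as well, with a median of −0.152 over 35 genes of which 7 were positive (adjusted p = 0.00193, but adjusted p = 0.812 with an estimated correlation). That sign held under every scaling, but the call was lost with quantile normalization (adjusted p = 0.36), with normexp (adjusted p = 0.319) and with the authors' value table (adjusted p = 0.0572). HNRNPC, a nuclear RNA-binding protein, differed by −0.34 (SE 0.0888, adjusted p = 0.122) and the splicing factor gene SNRPA by −0.41.

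The list of genes induced by low oxygen was not called (adjusted p = 0.138), but it was called upward without the array numbered 1 at 5% O2 (adjusted p = 0.0101), within slide 2 (adjusted p = 0.0149) and with the authors' value table (adjusted p = 0.0484). Of its 30 tested genes, 0 passed over all genes by limma, 1 was higher adjusted over the list alone and 3 had an unadjusted p under 0.05. BNIP3, a mitophagy receptor induced by HIF, was 0.84 higher at 20% O2 (SE 0.17, adjusted p = 0.063) and KDM3A, a histone demethylase induced by HIF, 0.41 higher (adjusted p = 0.262). Of 28 antioxidant genes 0 passed, 3 were higher and 1 lower adjusted over the list alone, and 7 had an unadjusted p under 0.05. HMOX1, heme oxygenase 1, differed by 2.42 with a wide error (SE 0.729, adjusted p = 0.162). Markers of cultured adherent cells had a median difference of 0.408 (adjusted p = 0.0955), which was 0.387 with slide as a block, 0.248 within slide 1 and 0.601 within slide 2. They were called upward with that block (adjusted p = 0.0208), within slide 2 (adjusted p = 0.000147), without the array numbered 1 at 5% O2 (adjusted p = 0.000108) and without that numbered 3 at 20% O2 (adjusted p = 0.00161). Markers of cumulus cells had a median difference of 0.462 (adjusted p = 0.152) and markers of stroma 0.0748 (adjusted p = 0.502). These move beside the p53 targets and beside ISG15, an interferon-stimulated ubiquitin-like protein that differed by 3.04 without passing (SE 1.12, adjusted p = 0.247).

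In this comparison 7 probes were higher and 18 lower. The split was 5 to 152 with the median as scale, where the median difference of all probes was −0.136 (−0.0226 with the 75th percentile as scale). The split was 2 to 0 with the authors' value table. With slide as a block 4 probes passed, within slide 1 0 (2387 at unadjusted p under 0.05 by limma) and within slide 2 1. Medians of p53 targets were 0.301, 0.436 and 0.27 in these fits, of ribosomal proteins −0.235, −0.321 and −0.177, and of mRNA processing −0.157, −0.116 and −0.175. The p53 call was lost within slide 1 (adjusted p = 0.069) and within slide 2 (adjusted p = 0.222), and that of mRNA processing within slide 1 (adjusted p = 0.388). The count fell to 2 without the replicate numbered 3 at 20% O2. It fell to 0 without any of the other 6 arrays, with 3061 to 4313 probes at unadjusted p under 0.05. None of the 5 genes kept its call without every array in turn, and 4 of them lost it with the authors' value table.

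With BOEC at 20% O2 against 20% O2 alone, the comparison that holds oxygen constant, CYP1B1 and CYP1A1 fell furthest. Both encode cytochrome P450 enzymes that are induced through the aryl hydrocarbon receptor. CYP1B1 (chromosome 11, 20493493 to 20499001 in UMD 3.1) fell by 6.59 (SE 0.282, adjusted p = 5.44e-07), at least 71.9-fold lower, from 0.15 ± 0.294 (SD, n = 3) to −6.44 ± 0.407 (SD, n = 3). CYP1A1 (chromosome 21, 34342808 to 34345682) fell by 4.18 (SE 0.373, adjusted p = 0.000606), at least 11.4-fold lower. CHI3L1, a secreted chitinase-like glycoprotein (chromosome 16, 771323 to 781451), rose by 5.65 (SE 0.291, adjusted p = 2.49e-06), at least 26.2-fold higher. CFB, complement factor B (chromosome 23, 27225270 to 27231292), rose by 4.67 (SE 0.792, adjusted p = 0.0147), at least 18.3-fold higher, with a standard deviation of 2.19 between the BOEC arrays. Its call was lost without the array numbered 2 at 20% O2 (adjusted p = 0.0578, up to 0.26 over the alternatives) and after normexp (1.47, adjusted p = 0.0851). Normexp left smaller changes of CHI3L1 (1.89), CYP1B1 (−2.95) and CYP1A1 (−1.04), all still called. In the authors' value table CYP1B1 fell by −3.69 and CYP1A1 by −1.58, both called. There 22 of the 31 genes followed changed less by over 1.5 times, and 4 lost their call.

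Other rises included the epithelial mucin gene MUC1 at 3.79 (SE 0.724, adjusted p = 0.0225). S100A7, a calcium-binding protein of epithelia, rose by 3.06 (SE 0.525, adjusted p = 0.0153), at least 5.72-fold, although its other probe differed by 0.827 without passing. SLCO2A1, the prostaglandin transporter, rose by 2.78 (SE 0.423, adjusted p = 0.0105), at least 4.52-fold. Falls included AKR1B1, an aldo-keto reductase, at −1.36 (SE 0.218, adjusted p = 0.0117), GSTM3, a glutathione transferase, at −1.23 (SE 0.183, adjusted p = 0.0105), PAG11 at −1.62 (SE 0.276, adjusted p = 0.0148) and GPR137C at −1.35 (SE 0.223, adjusted p = 0.0138). After normexp MUC1 rose by 1.22, while S100A7 (0.51, adjusted p = 0.12, up to 0.345 over the alternatives) and SLCO2A1 (0.43, adjusted p = 0.0953, up to 0.334) lost their calls. Over the alternatives the smallest change of GPR137C was −0.59. PAG11 and GPR137C are among the 3 that rose at 20% against 5% O2, and these comparisons share the arrays at 20% O2.

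Oxidative phosphorylation genes shifted upward with BOEC, with a median of 0.15 over 74 genes of which 64 were positive (adjusted p = 0.00031). However, with the authors' value table the list's median was −0.179, where that of all probes was −0.178 (0.0243 with the 75th percentile as scale). Its call was lost there (adjusted p = 0.738) and with an estimated correlation (adjusted p = 0.904). Of its 74 genes 0 passed alone by either adjustment and 12 had an unadjusted p under 0.05. The 2 lists called with the authors' value table were others and both pointed downward, the unfolded protein response (adjusted p = 0.0315) and the cell cycle (adjusted p = 0.00945). ATP5ME, a subunit of ATP synthase, differed by 0.39 (adjusted p = 0.0622). Ribosomal protein genes shifted upward with a median of 0.176 over 77 genes of which 69 were positive (adjusted p = 3.98e-08), and this sign flipped with quantile normalization, at −0.01, and with the authors' value table, at −0.169. The call was lost in both (adjusted p = 0.506 and 0.819), with normexp (adjusted p = 0.345), and with an estimated correlation (adjusted p = 0.837). Signal strength differed beside both shifts: the 75th percentile of an array's intensities was 267 to 311 with BOEC and 395 to 530 at 20% O2, and the 10 brightest probes held 2.52% to 2.65% and 2.02% to 2.18% of the signal. Of the 77 genes 0 passed alone by either adjustment and 18 had an unadjusted p under 0.05. RPL32 differed by 0.35 (adjusted p = 0.0946). Of 23 tested cell junction genes 2 rose, among them GJB5, a connexin, at 1.17 (SE 0.229, adjusted p = 0.0242), while 3 were higher adjusted over the list alone. Of 16 inner cell mass genes 2 rose, SPIC at 1.46 (SE 0.304, adjusted p = 0.0283) and DPPA4 at 1.0 (SE 0.234, adjusted p = 0.0422). FADS2, a fatty acid desaturase, was the only riser among 26 lipid genes at 1.30 (SE 0.224, adjusted p = 0.0157).

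Of 14 tested markers of oviduct epithelium 2 rose with BOEC, MUC1 and the keratin gene KRT7 at 1.59 (SE 0.284, adjusted p = 0.0172), both adjusted over the list alone and over all genes, and the list was not called (adjusted p = 0.325). Markers of stroma had a median difference of 0.0849 and a mean of −0.231 (0 of 16 passed by limma, 0 at unadjusted p under 0.05), markers of adherent cells a median of −0.133 with camera pointing upward (adjusted p = 0.905), and markers of cumulus cells 0.0301. For adherent markers the median was −0.19 with slide as a block, and its direction turned between slides, at 0.292 within slide 1 and −0.517 within slide 2, where the list was called downward (adjusted p = 0.0454). In all, 611 probes were higher and 360 lower, a split of 655 to 655 with quantile normalization, 988 to 896 with normexp and 337 to 2802 with the authors' value table. A slide block left 598 probes, slide 1 alone 0 (2959 at unadjusted p under 0.05 by limma) and slide 2 alone 5. Medians in these fits were 0.128, 0.162 and 0.122 for oxidative phosphorylation, whose call was lost within slide 2 (adjusted p = 0.105), and 0.166, 0.19 and 0.164 for ribosomal proteins. Every array left out lowered the count by more than 1.5 times, to 377, 262 and 225 without BOEC replicates 1, 2 and 3 and to 187, 304 and 178 without the replicates numbered 2, 3 and 4 at 20% O2. Without each array in turn CHI3L1, CYP1B1, CYP1A1, AKR1B1, GSTM3 and SLCO2A1 kept their calls, 6 of the 31 genes followed.

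**Figure D1:**
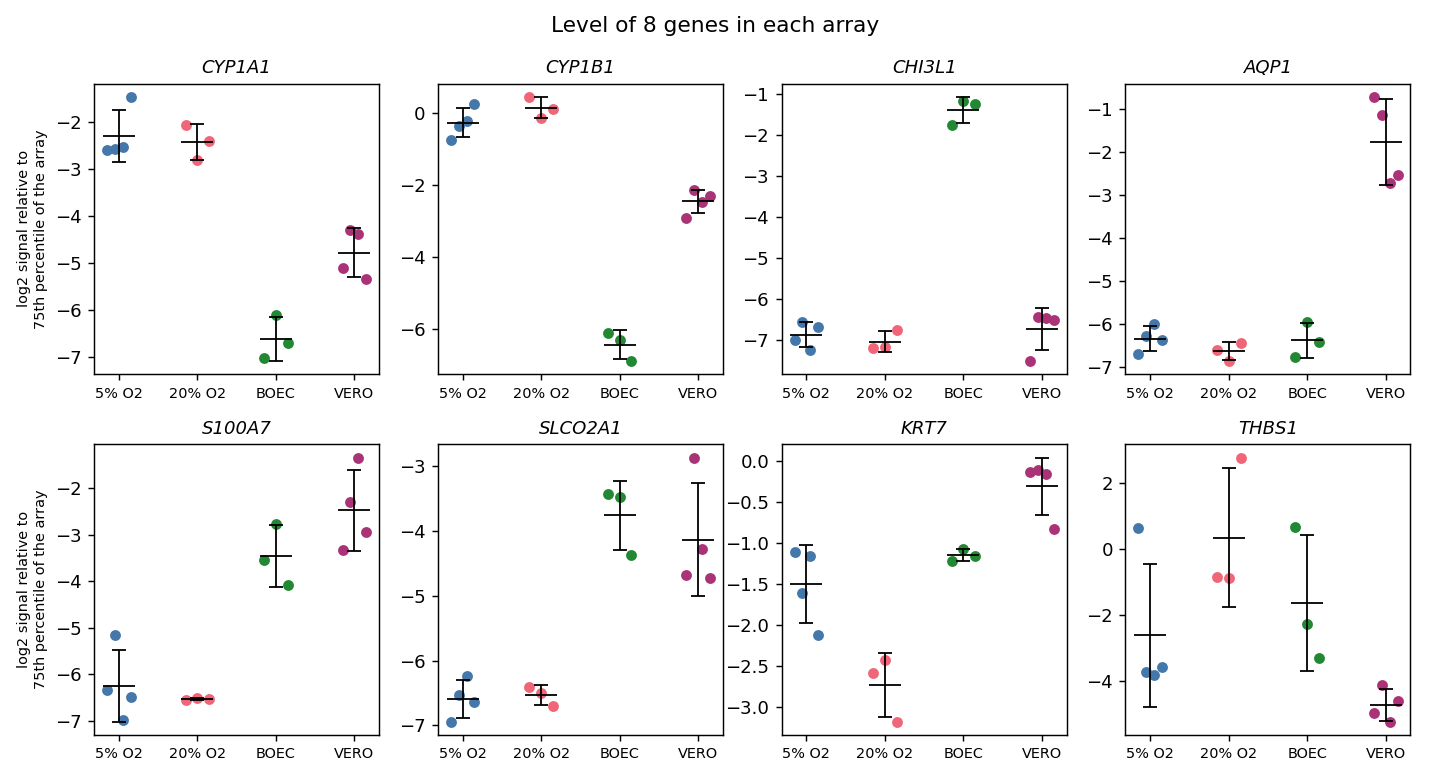
Level of 8 genes in the 14 arrays, on a vertical axis of log2 intensity relative to the 75th percentile of each array, for 5% O2, 20% O2, BOEC and VERO on the horizontal axis. Points are arrays, and the bar with its whiskers is the mean ± SD; CYP1B1 averaged 0.15 at 20% O2, −6.44 with BOEC and −2.46 with VERO cells, while CHI3L1 averaged −1.39 with BOEC and AQP1 −1.78 with VERO cells.

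With VERO cells against 20% O2 alone, AQP1, a water channel, rose by 4.86 (SE 0.425, adjusted p = 0.00056), at least 18.6-fold higher. S100A7 (chromosome 3, 16967602 to 16971446) rose by 4.04 (SE 0.491, adjusted p = 0.00109), at least 11.2-fold higher. The aldo-keto reductase gene AKR1B10 rose by 3.60 (SE 0.467, adjusted p = 0.00127), at least 6.5-fold and above background on 3 of 4 VERO arrays. LOXL1, which cross-links elastin, rose by 3.29 (SE 0.671, adjusted p = 0.0108), at least 9.79-fold, and FN1, fibronectin, by 2.51 (SE 0.513, adjusted p = 0.011), where all 5 other probes of FN1 were called too. KRT7 (chromosome 5, 27828982 to 27842880) rose by 2.43 (SE 0.266, adjusted p = 0.000848), and SLCO2A1 by 2.40 (SE 0.395, adjusted p = 0.00379), at least 3.48-fold and above background on 2 of 4 VERO arrays. CYP1B1 fell by 2.61 (SE 0.264, adjusted p = 0.000629). CYP1A1, outside the rule for named genes here and added after its values were seen, fell by 2.35 (SE 0.349, adjusted p = 0.0022), at least 5.08-fold lower. After normexp 34 of the 87 genes followed changed less by over 1.5 times, among them AQP1 (1.38), S100A7 (0.94), AKR1B10 (0.82) and LOXL1 (1.25), all still called, as was CYP1A1 (−0.72). SLCO2A1 lost its call there (0.37, adjusted p = 0.0785, up to 0.28 over the alternatives).

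The largest falls with VERO cells were in THBS1, thrombospondin 1, at −5.06 (SE 1.24, adjusted p = 0.0234), and VEGFC, a growth factor of lymphatic vessels, at −3.18 (SE 0.691, adjusted p = 0.0144). The G protein subunit gene GNGT2 fell as well, at −3.05 (SE 0.777, adjusted p = 0.0268), at least 5.45-fold, and so did COL1A2, a chain of type I collagen, at −2.65 (SE 0.772, adjusted p = 0.0443), with its other probe at −2.34 not called. THBS1 varied widely between arrays at 20% O2 (0.34 ± 2.09, SD, n = 3) and little with VERO cells (−4.71 ± 0.478, SD, n = 4). These genes moved beside marker lists of other cells. Markers of cultured adherent cells had a median difference of −0.547 with VERO cells (camera adjusted p = 0.208), −0.597 with slide as a block, −0.542 within slide 1 and −0.431 within slide 2. Of 23 tested 1 rose and 4 fell, or 2 and 7 adjusted over the list alone. Among the fallers on that list were CCN2, a matricellular protein, at −0.76 (SE 0.145, adjusted p = 0.00787) and ITGB1, an integrin subunit, at −0.88 (SE 0.201, adjusted p = 0.0176). Markers of stroma had a median of −0.173 (adjusted p = 0.59, 1 of 16 fell) and markers of cumulus cells −0.308 (adjusted p = 0.309, 1 of 12 fell, AMHR2 at −1.62, at least 2.53-fold). COL1A2, itself a stromal marker on the list, lost its call with the mean of these markers as a covariate (adjusted p = 0.0682) and without any 1 of the 7 arrays (adjusted p from 0.0501 to 0.189). Without the array numbered 4 at 20% O2, THBS1 (adjusted p = 0.103) and VEGFC (adjusted p = 0.0673) lost theirs, as THBS1 did without the VERO array numbered 1 (adjusted p = 0.0504), and over all alternatives these reached 0.539 and 0.315. After normexp the falls were −2.92 for THBS1, −1.18 for VEGFC and −0.72 for GNGT2.

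Of 74 oxidative phosphorylation genes 12 rose and 0 fell with VERO cells (4 lower at unadjusted p under 0.05 by limma), and 23 were higher and 2 lower adjusted over the list alone. With the 75th percentile as scale the list had a median of 0.238 (camera adjusted p = 8.14e-07). It was called upward under every scaling, though not with an estimated correlation (adjusted p = 0.837). SDHD, a subunit of succinate dehydrogenase, rose by 0.65 (SE 0.128, adjusted p = 0.00954), ATP5ME by 0.46 (SE 0.0971, adjusted p = 0.0126) and UQCR10, of complex III, by 0.49 (SE 0.108, adjusted p = 0.0156). Of 77 ribosomal protein genes 8 rose and 1 fell, or 16 and 1 adjusted over the list alone, with a median of 0.215 (adjusted p = 1.01e-08) that stayed positive under every scaling, at 0.00538 with quantile normalization. The ribosomal call was lost with quantile normalization (adjusted p = 0.352), with normexp (adjusted p = 0.319) and with an estimated correlation (adjusted p = 0.837). Beside these shifts the 75th percentile was 215 to 414 with VERO cells, overlapping that at 20% O2, and the share of the 10 brightest probes 2.16% to 2.64%. RPL22L1 rose by 0.56 (SE 0.116, adjusted p = 0.012), and RPL10L by 2.50 (SE 0.506, adjusted p = 0.0104) where its other probe differed by −0.191. Of 26 lipid metabolism genes 3 rose and 1 fell, the risers led by FADS2 at 1.17 (SE 0.209, adjusted p = 0.00584) and CPT1A, which admits fatty acids to mitochondria, at 0.82 (SE 0.196, adjusted p = 0.0214). Of 23 cholesterol synthesis genes 1 fell, ACAT2, and of 25 glycolysis genes 2 rose and 0 fell.

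Of 28 antioxidant genes 4 rose and 3 fell (4 and 7 adjusted over the list alone), with TALDO1, of the pentose phosphate pathway, at 0.76 (SE 0.127, adjusted p = 0.00401) and GSTM3 at −0.96 (SE 0.171, adjusted p = 0.00587). Of 21 unfolded protein response genes 1 rose and 3 fell, the riser being ASNS, asparagine synthetase, at 0.77 (SE 0.193, adjusted p = 0.0251). The fallers included DDIT3, a transcription factor of stress-induced death, at −0.60 (SE 0.125, adjusted p = 0.012) and EDEM1, of protein degradation from the endoplasmic reticulum, at −0.71 (SE 0.157, adjusted p = 0.0156). Of 20 apoptosis genes 1 rose and 2 fell, the same counts as adjusted over the list alone. Of 23 cell junction genes 4 rose and 1 fell (6 and 3 adjusted over the list alone), with the claudins CLDN6 at 1.25 (SE 0.201, adjusted p = 0.00335), CLDN7 at 1.02 (SE 0.189, adjusted p = 0.00703) and CLDN4 at −1.37 (SE 0.373, adjusted p = 0.0347). Of 16 inner cell mass genes 3 rose (5 adjusted over the list alone), SPIC at 1.76 (SE 0.284, adjusted p = 0.00342), DPPA4 at 1.16 (SE 0.219, adjusted p = 0.00763) and SOX2, a pluripotency factor, at 0.62 (SE 0.178, adjusted p = 0.0411). The list itself missed the threshold (adjusted p = 0.0868). Of 18 prostaglandin and steroid genes 2 rose and 4 fell, with PTGES, which makes prostaglandin E2, at 1.28 (SE 0.265, adjusted p = 0.0115). The fallers included AKR1B1 at −1.57 (SE 0.204, adjusted p = 0.00127) and the progesterone receptor PGR at −1.49 (SE 0.335, adjusted p = 0.0168).

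Of 22 interferon-stimulated genes 2 rose and 1 fell, while 2 were higher and 5 lower at unadjusted p under 0.05 by limma. The list leaned downward without being called, with a median of −0.325 and a mean of −0.791. OAS2, which makes the activator of RNase L, rose by 1.65 (SE 0.231, adjusted p = 0.00167), IRF1 rose by 1.18 (SE 0.277, adjusted p = 0.0202), and DDX58, a sensor of viral RNA also called RIG-I, fell by 1.48 (SE 0.198, adjusted p = 0.00139). Of 27 chromatin genes 2 rose and 1 fell, with TRIM28, a corepressor that silences retroelements, at 0.67 (SE 0.14, adjusted p = 0.0124) and the histone demethylase KDM4B at −0.99 (SE 0.206, adjusted p = 0.0122). Of 26 growth factor genes 2 rose and 3 fell, of 35 mRNA processing genes 4 rose and 0 fell, of 16 heat shock genes 1 rose and 1 fell, and of 37 cell cycle genes 1 rose and 1 fell. Of 21 trophectoderm, 11 primitive endoderm and 17 imprinted genes, 1 rose and 1 fell in each list, and of 24 genome activation genes 1 fell. Of 30 genes induced by low oxygen 1 fell, ANGPTL4 at −0.74 (SE 0.192, adjusted p = 0.0281), whose other probe differed by 0.596. Of 17 p53 targets and 28 maternal oocyte transcripts 0 passed by limma, and these lists had medians of −0.346 (camera adjusted p = 0.187) and −0.311 (adjusted p = 0.205). Of 14 oviduct epithelium markers 1 rose, KRT7, and 2 fell, and of 8 leukocyte markers 1 rose.

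In all, 2268 probes were higher and 1421 lower with VERO cells, a split of 2120 to 756 with the median as scale, 1973 to 1960 with quantile normalization and 917 to 1403 with the authors' value table. Blocking by slide left 3445 probes, slide 1 alone 0 (3870 at unadjusted p under 0.05 by limma) and slide 2 alone 2. The medians were then 0.224, 0.24 and 0.172 for oxidative phosphorylation and 0.211, 0.226 and 0.214 for ribosomal proteins. The count was 1715, 1959 and 1240 without the replicates numbered 2, 3 and 4 at 20% O2 and 2385 without VERO replicate 2. Of the 87 genes followed, 32 kept their calls without each array in turn, among them AQP1, S100A7, AKR1B10, LOXL1, FN1, KRT7, CYP1B1, OAS2, DDX58, TALDO1, GSTM3, SDHD and FADS2.

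**Figure D2:**
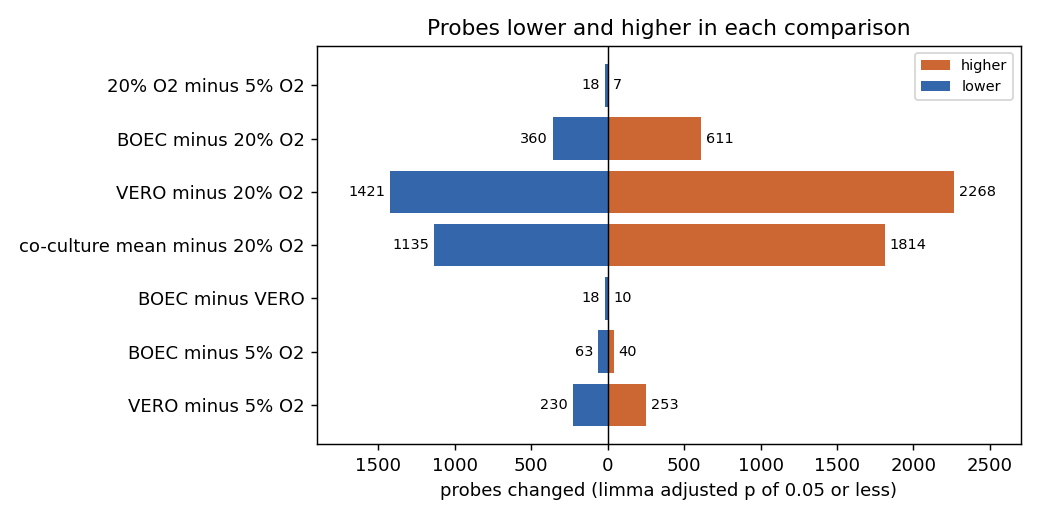
Number of probes that differed at limma's adjusted p of 0.05 or less in each comparison, on a horizontal axis with higher probes to the right of 0 and lower probes to the left. VERO against 20% O2 had the most (2268 higher, 1421 lower), and 20% against 5% O2 (7 and 18) and BOEC against VERO (10 and 18) the fewest.

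The mean of both co-cultures against 20% O2 is an average, which a large effect of 1 feeder can move alone. CYP1B1 fell by 4.60 (SE 0.239, adjusted p = 5.5e-06) and CYP1A1 by 3.26 (SE 0.316, adjusted p = 0.000707), at least 7.62-fold lower. S100A7 rose by 3.55 (SE 0.445, adjusted p = 0.00145), at least 8.02-fold, and was above background on all 7 co-culture arrays. SLCO2A1 rose by 2.59 (SE 0.358, adjusted p = 0.00198), at least 3.97-fold. PLAU, the urokinase plasminogen activator, rose by 2.23 (SE 0.278, adjusted p = 0.00145) and KRT7 by 2.01 (SE 0.241, adjusted p = 0.0014). The linker histone gene H1-3 rose by 2.27 (SE 0.405, adjusted p = 0.00651) and the calmodulin-like gene CALML5 by 2.63 (SE 0.34, adjusted p = 0.00154). AKR1B1 (chromosome 4, 99016785 to 99033590) fell by 1.47 (SE 0.185, adjusted p = 0.00146), PAG11 by 1.82 (SE 0.234, adjusted p = 0.00154), and DUSP6, a phosphatase of the ERK pathway, by 1.48 (SE 0.326, adjusted p = 0.0166). After normexp the changes of CYP1B1 (−2.42), CYP1A1 (−0.88), S100A7 (0.73), SLCO2A1 (0.40), PLAU (1.30) and H1-3 (0.59) were smaller and still called.

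Oxidative phosphorylation genes had a median of 0.2 (7 of 74 rose and 0 fell, 10 and 1 adjusted over the list alone, camera adjusted p = 1.15e-06, but adjusted p = 0.837 with an estimated correlation). It turned to −0.0576 with the authors' value table, where the call was lost (adjusted p = 0.432). The median of all probes was −0.112 in that table, beside 0.021 with the 75th percentile as scale. Ribosomal protein genes had a median of 0.206 (5 of 77 rose over all genes, 0 adjusted over the list alone, 31 at unadjusted p under 0.05 by limma, adjusted p = 6.57e-10), which turned to −0.0616 with the authors' value table. The 2 lists called there were again the unfolded protein response (adjusted p = 0.0441) and the cell cycle (adjusted p = 0.0308), both downward. The ribosomal call was lost in that table (adjusted p = 0.385), with quantile normalization (adjusted p = 0.358), with normexp (adjusted p = 0.313) and with an estimated correlation (adjusted p = 0.837). Markers of adherent cells had a median of −0.395 (adjusted p = 0.533), −0.438 with slide as a block, −0.24 within slide 1 and −0.707 within slide 2, where they were called (adjusted p = 0.0185), and markers of stroma a median of 0.0519 and a mean of −0.48.

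In this mean 1814 probes were higher and 1135 lower, a split of 1661 to 1798 with quantile normalization, 1875 to 2039 with normexp and 864 to 3047 with the authors' value table. The slide block left 2531 probes, slide 1 alone 0 (3464 at unadjusted p under 0.05 by limma) and slide 2 alone 2. Medians were 0.181, 0.21 and 0.175 for oxidative phosphorylation and 0.202, 0.221 and 0.19 for ribosomal proteins. The count was 1090, 1506 and 1020 without the replicates numbered 2, 3 and 4 at 20% O2, and 25 of 73 genes, all those named here except DUSP6 among them, kept their calls without each array in turn.

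Of the probes higher with BOEC and with VERO cells against 20% O2, 510 were shared, from 611 and 2268, where 44.3 would be shared by independent lists, and of the lower ones 241 were shared, from 360 and 1421, where 16.4 would be. Both comparisons use the same 3 arrays at 20% O2. Across 31224 probes the covariance of the 2 effects was 0.164 (r = 0.611), and groups simulated without any effect against those arrays gave 0.0718 (r = 0.535) over 100 simulations, a difference of 0.0926. Computed from the design it was 0.0929 with a jackknife SD of 0.0644 over arrays left out in turn, and was thus not clearly larger than its error. As 3 arrays cannot be split into pairs, part of the excess over either value may come from the shared arrays. Against 5% O2 the covariance was 0.0775 (r = 0.42) beside a simulated 0.0535 (r = 0.46), and with the 4 arrays at 5% O2 split between the comparisons it ranged from 0.0013 to 0.0513 (r from 0.005 to 0.242) over the 6 splits. Probes are not independent replicates in these correlations.

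The direct comparison of BOEC with VERO cells tested where the feeders differed. CHI3L1 was 5.34 higher with BOEC (SE 0.273, adjusted p = 4.39e-06), at least 20.3-fold, and TFPI2, a Kunitz-type protease inhibitor (chromosome 4, 11035479 to 11039782), 4.41 higher (SE 0.428, adjusted p = 0.00141), at least 13.1-fold. LTF, lactoferrin, was 1.72 higher (SE 0.261, adjusted p = 0.033). AQP1 was lower with BOEC by −4.60 (SE 0.425, adjusted p = 0.00102), at least 17.4-fold. CYP1B1 was lower by −3.98 (SE 0.264, adjusted p = 4.66e-05), at least 11.8-fold, although its other probe differed by −0.894 without passing. AKR1B10 was lower by −3.40 (SE 0.467, adjusted p = 0.0258), at least 6.11-fold. RPL10L, at −3.12 (SE 0.506, adjusted p = 0.0499), the retinol dehydrogenase gene SDR16C5, at −1.88 (SE 0.276, adjusted p = 0.0304), and the adaptor gene ARRB2, at −0.67 (SE 0.0933, adjusted p = 0.0262), were lower too. MUC1 differed by 4.04 without passing (SE 0.677, adjusted p = 0.0584), and CYP1A1 was below background with both feeders. After normexp the differences were 1.88 for CHI3L1, 1.14 for TFPI2, 0.77 for LTF, −1.34 for AQP1, −1.08 for CYP1B1, −1.93 for RPL10L and −0.54 for SDR16C5, all called. AKR1B10 lost its call there (−0.83, adjusted p = 0.07, up to 0.429 over the alternatives).

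Interferon-stimulated genes were higher with BOEC than with VERO cells, with a median of 0.593 over 22 genes of which 16 were positive (camera adjusted p = 0.0121, but adjusted p = 0.812 with an estimated correlation), a sign kept under every scaling. Over all genes 0 members passed by limma, 10 had an unadjusted p under 0.05, and 6 were higher and 1 lower adjusted over the list alone. XAF1, an interferon-induced factor of apoptosis, differed by 2.28 (SE 0.51, adjusted p = 0.106), at least 4.21-fold and above background on 2 of 3 BOEC arrays, IRF9, a subunit of the complex that activates these genes, by 0.53 (adjusted p = 0.141), and IRF7 by −0.63 (adjusted p = 0.0994). The list was also not called without BOEC replicate 1 (adjusted p = 0.153), over probes above background on all 14 arrays (adjusted p = 0.113) or within slide 2 (adjusted p = 0.639). Markers of other cells moved beside it. Markers of adherent cells were higher with BOEC, with a median of 0.304 over 23 genes of which 19 were positive (adjusted p = 0.039, but adjusted p = 0.957 with an estimated correlation, sign kept under every scaling). Of these, 0 passed over all genes by limma, 7 had an unadjusted p under 0.05, and 3 were higher and 1 lower adjusted over the list alone. This call was lost without BOEC replicate 1 (adjusted p = 0.754), VERO replicate 3 (adjusted p = 0.154) or VERO replicate 4 (adjusted p = 0.067). ANXA1, an annexin, differed by 3.17 (SE 0.978, adjusted p = 0.171) and ITGB1 by 0.75 (adjusted p = 0.14). Markers of cumulus cells had a median of 0.48 (adjusted p = 0.0614) and markers of stroma 0.277 (adjusted p = 0.249). With the stromal score as covariate the interferon list stood at adjusted p = 0.0777 and the adherent list at adjusted p = 0.596.

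Between the feeders 10 probes were higher and 18 lower with BOEC, a split of 5 to 23 with the median as scale and 9 to 77 with the authors' value table. In that table the median difference of all probes was −0.118, beside 0.00449 with the 75th percentile as scale. With the replicate number as a block 73 probes and 6 lists passed, against 28 and 2 without it, while SDR16C5 (adjusted p = 0.0548, up to 0.429 over the alternatives) and SIPA1L1 (adjusted p = 0.0575, up to 0.541) lost their calls. With slide as a block 28 probes passed, within slide 1 0 (3205 at unadjusted p under 0.05 by limma) and within slide 2 1, and medians were 0.556, 0.805 and 0.16 for the interferon list and 0.253, 0.564 and −0.0615 for adherent markers, the latter not called with the block (adjusted p = 0.0976), within slide 2 (adjusted p = 0.947) or with array weights (adjusted p = 0.0503). The count was 10, 16 and 13 without BOEC replicates 1, 2 and 3, and 13, 15 and 96 without VERO replicates 1, 3 and 4. CHI3L1, TFPI2, AQP1 and CYP1B1, 4 of the 14 genes named by the rule, kept their calls without each array in turn.

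**Figure D3:**
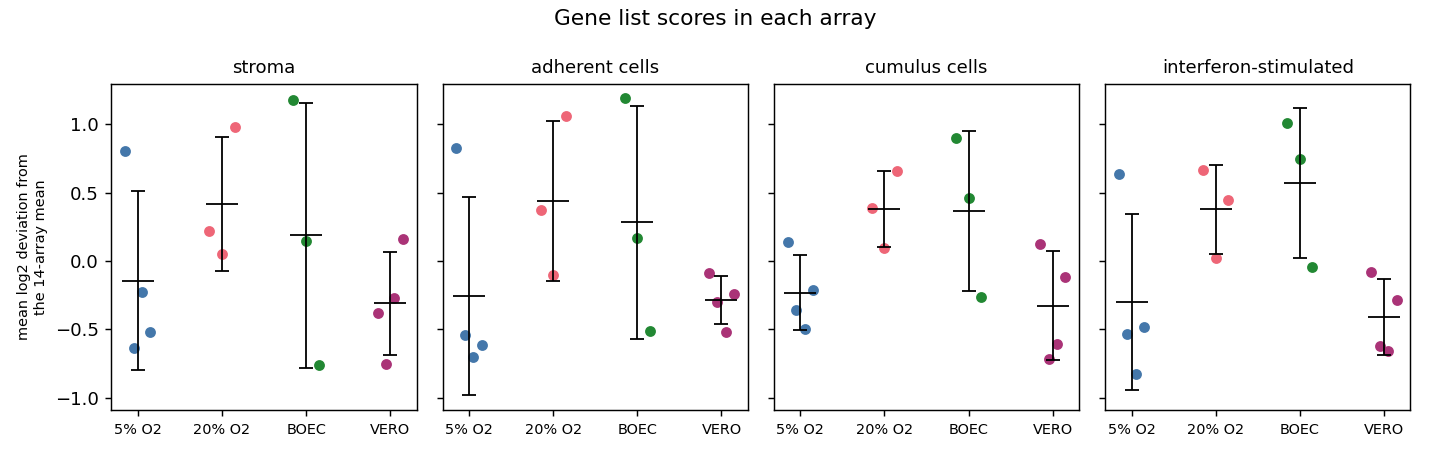
Scores of 4 gene lists in the 14 arrays by group, where the vertical axis is the mean log2 deviation of a list's genes from their mean over all arrays. Points are arrays and bars are the mean ± SD; the interferon-stimulated scores with BOEC were 1.01, 0.744 and −0.044, and those with VERO cells lay between −0.662 and −0.078.

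Against the control condition, 5% O2, each co-culture differed in oxygen and in feeder together. With BOEC, CHI3L1 rose by 5.48 (SE 0.273, adjusted p = 1.61e-06), at least 23.5-fold, CFB by 4.58 (SE 0.741, adjusted p = 0.0347), at least 16.3-fold, and TFPI2 by 4.06 (SE 0.428, adjusted p = 0.00346), at least 11.4-fold. CXCL3, a neutrophil chemokine, rose by 2.98 (SE 0.506, adjusted p = 0.038), at least 5.11-fold, SLCO2A1 by 2.84 (SE 0.395, adjusted p = 0.0157), at least 4.57-fold, and PLAU by 2.10 (SE 0.307, adjusted p = 0.0206). CYP1B1 fell by 6.17 (SE 0.264, adjusted p = 5.32e-07), at least 53.9-fold, and CYP1A1 by 4.31 (SE 0.349, adjusted p = 0.000309), at least 12.5-fold. CRACD, a regulator of actin capping, fell by 1.49 (SE 0.198, adjusted p = 0.0117) and CD320, the transcobalamin receptor, by 1.17 (SE 0.149, adjusted p = 0.0103). After normexp the changes were 1.81 for CHI3L1, 1.06 for TFPI2, 0.61 for CXCL3, 1.16 for PLAU, −2.59 for CYP1B1, −1.14 for CYP1A1 and −0.74 for CRACD, all called. CFB (1.46, adjusted p = 0.147, up to 0.283 over the alternatives) and SLCO2A1 (0.49, adjusted p = 0.111, up to 0.418) lost their calls there. Interferon-stimulated genes had a median of 0.599 over 22 genes of which 18 were positive (camera adjusted p = 0.0115, but adjusted p = 0.812 with an estimated correlation, sign kept under every scaling). Of these, 0 passed over all genes by limma, 8 had an unadjusted p under 0.05, and 5 were higher and 1 lower adjusted over the list alone. XAF1 differed by 2.29 (SE 0.51, adjusted p = 0.0865), at least 3.62-fold, and IRF9 by 0.55 (adjusted p = 0.134). That call was lost without BOEC replicate 1 (adjusted p = 0.153), without the replicate numbered 3 at 5% O2 (adjusted p = 0.0754), over probes above background on all 14 arrays (adjusted p = 0.117) and within slide 2 (adjusted p = 0.317). Markers of adherent cells moved beside it with a median of 0.348 (adjusted p = 0.0751), 0.242 with slide as a block, 0.339 within slide 1 and 0.00844 within slide 2, and were called without the array numbered 1 at 5% O2 (adjusted p = 0.00012) and without BOEC replicates 2 (adjusted p = 0.0328) or 3 (adjusted p = 0.000507). Beside them were markers of cumulus cells, with a median of 0.565 (adjusted p = 0.0868), and markers of stroma with 0.282 (adjusted p = 0.324).

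For BOEC against 5% O2, 40 probes were higher and 63 lower, a split of 41 to 299 with the median as scale, 33 to 103 with quantile normalization and 103 to 2516 with the authors' value table. With the first and last of these the median difference of all probes was −0.166 and −0.198, beside −0.0073 with the 75th percentile as scale. With slide as a block 60 probes passed, within slide 1 0 (2722 at unadjusted p under 0.05 by limma) and within slide 2 4, and interferon medians were 0.502, 0.745 and 0.244. The count was 24, 16 and 32 without BOEC replicates 1, 2 and 3 and 55, 32, 23 and 63 without the replicates numbered 1, 2, 3 and 4 at 5% O2. CHI3L1, TFPI2, CYP1B1, CYP1A1 and CD320, 5 of 20 genes, kept their calls without each array in turn.

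With VERO cells against 5% O2, SPP1, osteopontin (chromosome 6, 38120578 to 38127577), rose by 6.43 (SE 0.989, adjusted p = 0.0151), at least 53.4-fold. AQP1 rose by 4.56 (SE 0.393, adjusted p = 0.00151), at least 17.4-fold, S100A7 by 3.76 (SE 0.455, adjusted p = 0.00451), at least 9.81-fold, and AKR1B10 by 3.43 (SE 0.433, adjusted p = 0.00554), at least 5.83-fold. PLAU rose by 2.38 (SE 0.284, adjusted p = 0.00451) and RPL10L by 3.88 (SE 0.468, adjusted p = 0.00451). CYP1A1 fell by 2.48 (SE 0.323, adjusted p = 0.00676), at least 5.58-fold, CYP1B1 by 2.19 (SE 0.244, adjusted p = 0.00355), CD8B, a T-cell coreceptor subunit, by 1.60 (SE 0.225, adjusted p = 0.0115) and DDX58 by 1.14 (SE 0.184, adjusted p = 0.017). After normexp the changes were 2.57 for SPP1, 1.34 for AQP1, 0.87 for S100A7, 0.79 for AKR1B10, 1.40 for PLAU, 2.04 for RPL10L, −0.82 for CYP1A1 and −0.46 for DDX58, all called. Oxidative phosphorylation genes had a median of 0.143 over 74 genes of which 56 were positive (camera adjusted p = 3.15e-05, but adjusted p = 0.884 with an estimated correlation, sign kept under every scaling, though at only 0.00389 with the authors' value table). Of these, 1 rose and 0 fell over all genes by limma (2 lower at unadjusted p under 0.05), NDUFA2 at 0.79 (SE 0.132, adjusted p = 0.0184), or 3 and 0 adjusted over the list alone. That call was lost with the authors' value table (adjusted p = 0.0539), and UQCR11 differed by 0.81 without passing (adjusted p = 0.0678).

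For VERO cells against 5% O2, 253 probes were higher and 230 lower, a split of 89 to 150 with the median as scale and 108 to 219 with the authors' value table. With slide as a block 413 probes passed, within slide 1 0 (3456 at unadjusted p under 0.05 by limma) and within slide 2 1, and medians for oxidative phosphorylation were 0.143, 0.0781 and 0.2, without a call within slide 1 (adjusted p = 0.068). The count was 307, 127, 96 and 182 without the replicates numbered 1, 2, 3 and 4 at 5% O2 and 92, 227 and 253 without VERO replicates 1, 2 and 3. In all, 12 of 30 genes kept their calls without each array in turn, among them SPP1, AQP1, RPL10L, S100A7, AKR1B10, PLAU, CYP1A1, CYP1B1 and CD8B. Of the probes higher with BOEC and with VERO cells against 5% O2, 13 were shared where 0.324 would be by independent lists, and of the lower ones 27 where 0.464 would be. Both comparisons use the same 4 arrays at 5% O2, and part of the excess may come from them.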

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

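Of the tests below, those of scaling, feeder RNA, the relation of marker scores within groups, slide, the stromal score as a covariate and the count of gaps above background were chosen only after the result was seen. The predictions for receptor targets and for other splits of the arrays were written before those tests were run. The receptor targets were taken up to explain a fall that had already been seen in these data.

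The pattern a biologist may most want to follow is the fall of CYP1A1 and CYP1B1 with both feeders. The size changed with normexp and quantile normalization together, where CYP1A1 with VERO cells had the smallest fall of −0.717, and with the authors' value table (−1.18), but little by scaling alone (−2.29 with the median, −2.3 with quantiles), and the direction held, since all 16 changes stayed negative and called. Fewer stromal cells in the feeder groups are argued against, since with the stromal score as a covariate at least 98.9% of each fall was left. Lower activity of the aryl hydrocarbon receptor stays open: 7 other measured targets had a median of −0.349 with BOEC (SE 0.222) and 0 of them fell by limma at adjusted p of 0.05, while with VERO cells 3 fell, TIPARP at −1.19, ALDH3A1 at −1.21 and NFE2L2 at −0.777, and UGT1A1 rose by 0.562. Medium conditioned or cleared by the feeders is a biological explanation that was not tested.

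Another pattern is the set of 14 genes that differed between the feeders, each by limma's test of the difference itself. CHI3L1 (5.34), TFPI2 (4.41), LTF (1.72), NEXN (1.45) and SIPA1L1 (0.789) were higher with BOEC, while AQP1 (−4.6), CYP1B1 (−3.98), AKR1B10 (−3.4), RPL10L (−3.12), SDR16C5 (−1.88), SHROOM1 (−1.24), GRK6 (−1.12), C15orf39 (−0.88) and ARRB2 (−0.672) were lower. Scaling is argued against as the whole cause, since at least 11 of the 14 stayed called under each of the 4 other scalings; with the replicate number as a block 2 lost their call, SIPA1L1 (adjusted p = 0.0575, up to 0.541 over the alternatives) and SDR16C5 (adjusted p = 0.0548, up to 0.429). RNA of feeder cells carried over with the embryos could raise such transcripts: of 23 oviduct epithelium markers on the array, a list fixed before the test, 7 were dim in every array without feeders, but none of the 7 passed the filter for testing, so the 0 that rose with BOEC decides nothing. That explanation stays open, as 12 of the 14 tested markers on the list were above background on all 14 arrays, with the brightest probes those of EPCAM (1.74), CAPS (1.55) and TPPP3 (1.3).

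Stromal and adherent-cell transcripts differed between arrays of the same group, and several genes that fell with VERO cells are of that kind. Somatic cells in some pools may account for the spread within groups: the adherent score followed the stromal score within groups over 14 arrays (r = 0.899, permutation p = 0.0068; rho = 0.767, permutation p = 0.0108; adjusted p = 0.0175 and 0.027 over 5 relations), and r was 0.776 without the 2 arrays farthest from the median. The cumulus score followed it as well (r = 0.81, adjusted p = 0.0175; rho = 0.767, adjusted p = 0.027), the interferon score did so by r (0.771, adjusted p = 0.0292, 0.572 without those 2 arrays) but not by rank (rho = 0.657, adjusted p = 0.0777), and those of oviduct epithelium (r = −0.173, permutation p = 0.518) and leukocytes (r = 0.0261, permutation p = 0.917) missed the threshold. Whether embryos or other cells gave this signal was not separated: 10 of 16 tested stromal and 17 of 23 adherent markers were above background on all 14 arrays, 1 of each list is on another list, and the brightest probes, which do not rank abundance, were those of DCN (0.319), DES (−0.277) and ACTA2 (−0.359), and of SPARC (5.42), ANXA2 (5.29) and TAGLN2 (4.72). Slide held 3.55% of the variance of the stromal score within groups, which argues against slide for that score only. The share was not computed for the adherent score, whose list had medians with BOEC against 20% O2 of 0.292 within slide 1 and −0.517 within slide 2. With the stromal score as a covariate, the median of the 10 largest falls with VERO cells went from −2.66 to −1.9 (−1.74 to −2.26 without each array in turn). Of the 10, 5 kept their call, and 2 to 6 without each array in turn. A score of 16 genes measures somatic cells only roughly, so they stay open as the whole or part of the cause.

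No other split of the same arrays gave as many probes as the real one in 20% against 5% O2 (25 against 3 in the highest other split), VERO against 20% O2 (3689 against 1160), the mean of both co-cultures against 20% O2 (2949 against 443), VERO against 5% O2 (483 against 2) and the F test over all groups (2096 against 11). This argues against chance without excluding it. For 2 groups with 35 splits, 1 in 35 is the smallest share possible, and no adjustment was made over the tests. The splits also take the arrays as independent, and the count for 20% against 5% O2 was 0 to 2 without each array in turn. For BOEC against VERO, where the replicate numbers pair the arrays, the 8 splits that part all 3 pairs are too few, with 28 probes against 2 and 2 lists against 2, where 4 splits had as many lists. The 27 others keep a pair together and gave up to 3 probes and 5 lists. Of these, 0 gave as many probes as the real split and 21 as many lists. For BOEC against 20% O2 the 10 splits are too few, with 971 probes against 6 and 2 lists against 10, where 9 splits had as many lists. Chance was not argued against for BOEC against 5% O2, where 2 of 35 splits gave as many probes: exchanging the array numbered 1 at 5% O2 with that numbered 3 with BOEC gave 375 against the real 103, which points to a structure of the samples. Nor was it argued against for the other counts of lists: 28 of 35 splits gave as many for 20% against 5% O2 (3, highest other 11), 21 of 35 for VERO against 20% O2 (2, highest other 7), and 65 of 100 for the co-culture mean (2, highest other 13). As many came from 34 of 35 for BOEC against 5% O2 (1, highest other 9) and 29 of 35 for VERO against 5% O2 (1, highest other 9).

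A single array lay far from the other 3 of its group in 26 of 360 groups of values tested by Dixon's ratio, where chance gives about 18. In 78 of the groups an array was not well above background, so that its value is a bound and the order of dim arrays says nothing; among the 282 others 20 stood apart, where chance gives about 14.1. At 5% O2 the array numbered 1 stood apart, on the log2 scale, for THBS1 (0.628, others −3.79 to −3.57), VEGFC (−2.02, others −4.26 to −4.23), TPC3 (−1.58), PRPF31 (0.919), DDIT3 (4.46) and AQP3 (6.96), and for the scores of adherent markers (0.824, others −0.703 to −0.538), glycolysis (0.632) and cholesterol synthesis (0.27). MARCH11 (−1.32) and ARHGAP36 (−3.75), above background on 3 and 1 of the 4 arrays, had gaps of that kind that rest partly on bounds. In the same group the array numbered 4 stood apart for CYP1A1 (−1.48, others −2.61 to −2.53), KDM4B (−2.22), TSKS (0.411) and the apoptosis score (0.115), and the array numbered 2 for the oviduct epithelium score (−0.0878). Among VERO arrays, that numbered 1 stood apart for TKT (8.52) and RPL18 (8.24), that numbered 4 for KRT7 (−0.833) and ATP5ME (6.36), and that numbered 3 for SNURF (3.93) and ITGB1 (1.01). Of the gaps at the floor, those of CHI3L1 (−7.51) and TFPI2 (−7.24) on the VERO array numbered 1 and FUT6 (−4.8) on the array numbered 1 at 5% O2 carry no order, since these genes were not well above background on any array of their group, and the value of PTPRK on the VERO array numbered 4 (−5.46) is a bound, the gene being well above background on the 3 others.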

How the results depend on the processing

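Each slide on its own, 2 arrays left out together (the array numbered 1 at 5% O2 and that numbered 3 with BOEC) and the stromal score as a covariate were tests chosen only after the result was seen, and the other alternatives were planned. Values below are those that moved by over 1.5 times, and apart from alternatives that test fewer probes or arrays, or add a threshold, the cause was not tested. Over 260 results for named genes, 3833 settings kept direction and call, 2018 kept the direction without the call and 0 reversed. Many of these genes were chosen because their 2 groups of arrays did not overlap. For them, leaving arrays out, weighting arrays or fitting 1 slide could not reverse the direction. Other filters and limma's trend option left the differences as they were. Only other scalings, blocks and the covariate could have reversed those genes. Signal over background limits the dimmest genes, since 51.9% to 62.1% of probes were well above it on an array.

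With the median as scale, 157 probes differed for 20% against 5% O2, 467 for BOEC against 20% O2, 340 for BOEC against 5% O2 and 239 for VERO against 5% O2. Lists numbered 7 for 20% against 5% O2, 4 for BOEC against VERO and 4 for BOEC against 5% O2. Quantile normalization gave 16 probes for 20% against 5% O2, 4 lists for BOEC against 5% O2, and 1 list for BOEC, VERO and their mean against 20% O2. After normexp the counts were 179 for 20% against 5% O2, 1884 for BOEC against 20% O2, 46 for BOEC against VERO, 198 and 849 for BOEC and VERO against 5% O2, and 3394 for the F test. There were 4 lists for BOEC against 5% O2 and 1 for each of the 3 comparisons with 20% O2. The authors' value table gave 2, 3139 and 2320 probes for 20% against 5% O2, BOEC and VERO against 20% O2, 86 for BOEC against VERO, 2619 for BOEC against 5% O2 and 3563 for the F test. It called 7 lists for 20% against 5% O2, BOEC against VERO and BOEC against 5% O2, and 0 (3 at unadjusted p under 0.05 by camera) for VERO against 5% O2. For BOEC and the mean against 20% O2 it called 2 other lists, both lower, and lost the 2 called higher with the 75th percentile.

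Without a filter on dim probes, 20% against 5% O2 had 0 probes (4063 at unadjusted p under 0.05 by limma), BOEC, VERO and their mean against 20% O2 had 248, 1498 and 1523, BOEC against VERO 14, BOEC and VERO against 5% O2 32 and 70, and the F test 705. Lists numbered 5 for 20% against 5% O2 and 2 for BOEC against 5% O2. With probes above background on all 14 arrays, 318 differed for 20% against 5% O2, 1597 for BOEC against 20% O2, and 168 and 812 for BOEC and VERO against 5% O2, with 1 list for BOEC against VERO and 3 for BOEC against 5% O2. Limma's trend and robust options gave 392, 1631, 82, 196 and 855 probes for 20% against 5% O2, BOEC against 20% O2, BOEC against VERO, and BOEC and VERO against 5% O2, and 3477 for the F test. Array weights gave 735 for 20% against 5% O2, 2978 for BOEC and 4760 for the mean against 20% O2, 75 for BOEC against VERO, 954 and 788 for BOEC and VERO against 5% O2 and 4922 for the F test. They gave 6, 1 and 3 lists for 20% against 5% O2, BOEC against VERO and BOEC against 5% O2. Requiring a log2 change of 1 as well left 10 for 20% against 5% O2, 380, 1153 and 799 for BOEC, VERO and their mean against 20% O2, and 58 and 161 for BOEC and VERO against 5% O2. Fitting only the arrays compared gave 2 for 20% against 5% O2, 1507 for VERO against 20% O2, 4 for BOEC against VERO, and 5 and 52 for BOEC and VERO against 5% O2. Camera with an estimated correlation and fry each called 0 lists in all 7 comparisons, with 0 to 3 and 0 to 13 lists at unadjusted p under 0.05.

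Slide as a block gave 4 probes and 7 lists for 20% against 5% O2, 598 probes for BOEC against 20% O2 and 60 for BOEC against 5% O2. Within slide 1 all 7 comparisons and the F test had 0 probes (2387 to 3870 at unadjusted p under 0.05 by limma), with 4 lists for BOEC against VERO and 0 for VERO against 5% O2 (3 at unadjusted p under 0.05 by camera). Within slide 2 the counts were 1, 5, 2, 2, 1, 4 and 1 in the order of the comparisons and 3 for the F test, with 7 lists for 20% against 5% O2, 4 for VERO against 20% O2 and 1 for BOEC against VERO. These fits hold a lone array at 20% O2 on slide 1 and with BOEC on slide 2, which is assumed to vary like the other groups. Leaving out the 2 arrays together gave 0 probes for 20% against 5% O2 (4153 at unadjusted p under 0.05 by limma), 273 for BOEC against 20% O2, 60 for BOEC against VERO and 274 for VERO against 5% O2. It gave 9, 6, 9 and 2 lists for 20% against 5% O2, BOEC against VERO, and BOEC and VERO against 5% O2. The stromal score as a covariate gave 0 probes (3903 at unadjusted p under 0.05 by limma) and 5 lists for 20% against 5% O2, 1792 probes for VERO against 20% O2 and 1230 for the F test.

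With the replicate number as a block, BOEC against VERO, the only pair of groups that met the preset rule for pairing, had 73 probes and 6 lists. Correlations of same-numbered arrays ran from −0.112 to 0.322 between 5% and 20% O2, −0.0977 to 0.493 between 5% O2 and BOEC, −0.0691 to 0.22 between 5% O2 and VERO, 0.091 to 0.286 between 20% O2 and BOEC (only 2 pairs) and 0.0224 to 0.204 between 20% O2 and VERO. Their median was below that of other pairs between 5% and 20% O2 (−0.0192 against 0.0152). It was above it between 5% O2 and BOEC (0.238 against −0.113) and 5% O2 and VERO (0.0971 against −0.02435). The same held between 20% O2 and BOEC (0.1885 against −0.0935) and 20% O2 and VERO (0.166 against −0.0214). Pairing by number is thus not excluded in these other comparisons. There the block gave 0 probes (4603 at unadjusted p under 0.05 by limma) and 9 lists for 20% against 5% O2, 5 lists for VERO against 20% O2, 54 probes and 4 lists for BOEC against 5% O2 and 286 probes for VERO against 5% O2.

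Leaving out each array in turn, the counts of probes ranged from 0 to 2 for 20% against 5% O2 (3061 to 4313 at unadjusted p under 0.05 by limma where 0), and 178 to 377, 1240 to 4058 and 1020 to 3170 for BOEC, VERO and their mean against 20% O2. They ranged from 10 to 96 for BOEC against VERO, 16 to 63 and 92 to 524 for BOEC and VERO against 5% O2 and 845 to 2651 for the F test. Lists ranged from 3 to 7 for 20% against 5% O2, 2 to 3 for each comparison with 20% O2, 1 to 4 for BOEC against VERO and 0 to 5 for BOEC against 5% O2 (4 to 5 at unadjusted p under 0.05 by camera where 0), and stayed at 1 for VERO against 5% O2. The covariance of the BOEC and VERO effects less what the shared arrays at 20% O2 add by the design, 0.0929, ranged from 0.055 to 0.124, and it was 0.051 after normexp, 0.0327 within slide 1 and 0.14 within slide 2.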

Other observations

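Both groups of probes below were chosen, and tested, only after the result was seen. Of probes for replication-dependent histones, whose mRNAs are made in S phase, 76 were tested. Against 20% O2, 45 rose and 0 fell with VERO cells (53 at unadjusted p under 0.05 by limma, median 0.634). With BOEC 18 rose and 0 fell (42 at unadjusted p under 0.05, median 0.349). Their medians stayed positive under the other scalings, lowest at 0.445 with VERO cells and 0.0399 with BOEC, both in the authors' value table. At 20% against 5% O2 the median was −0.502, where 0 passed (42 at unadjusted p under 0.05 by limma), 8 were lower with the median as scale and 6 after normexp. Against 5% O2, 7 rose with VERO cells (median 0.167), while with BOEC 0 passed (26 at unadjusted p under 0.05 by limma, median −0.126) and 15 were lower and 1 higher in the authors' value table (median −0.39). Of 17 probes for replacement histones, which are made outside S phase too, 2 rose and 2 fell with VERO cells (median −0.0495). That became 2 and 6 with quantile normalization (median −0.198) and after normexp (median −0.192). With BOEC 1 rose and 0 fell (median −0.0896), or 1 and 4 in the authors' value table (median −0.464).

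Of 715 tested probes that the array design names after endogenous retroviruses, 191 rose and 1 fell with VERO cells against 20% O2 (median 0.456). Among the 30534 other probes 2077 were higher and 1420 lower. With BOEC 58 of the 715 rose and 0 fell (205 at unadjusted p under 0.05 by limma, median 0.274). That median turned to −0.0358 in the authors' value table, where 17 rose and 1 fell. With VERO cells the median kept its sign under all 4 other scalings, from 0.282 in the authors' value table to 0.515 with the median as scale. Against 5% O2, 3 rose with VERO cells (median 0.194) and 1 with BOEC (median 0.0131). The count with VERO cells was 20 after normexp and 0 under the 3 other scalings (54 to 132 at unadjusted p under 0.05 by limma), and the BOEC median turned to −0.145 with the median as scale and −0.22 in the authors' value table, where 28 were lower. Between 20% and 5% O2 0 passed by limma (131 at unadjusted p under 0.05, median −0.261). The feeders did not differ at these probes by limma's adjusted p, with 0 called (3 lower with BOEC in the authors' value table), 257 at unadjusted p under 0.05 and a median of −0.159, which does not show that they act alike.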
